A study of Mus musculus with 8 samples.

How the data were processed

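Poly(A) RNA of mouse MA9 leukemia cells, grown with 15% fetal bovine serum, IL-3, IL-6 (10 ng/mL) and SCF (20 ng/mL), was sequenced with paired reads of 65 bp, per the labels' protocols. The library kit named in the labels does not mark strand, so overlapping and antisense genes cannot be told apart. The authors deposited whole-number counts per Ensembl gene, not normalized, for 8 libraries in 1 table. The submitters' processing notes name the build mm10 and the tools kallisto, HTSeq and DESeq2, with no versions. Which tool made the counts, the annotation and the assembly used for alignment are not given in the sources used here. Columns were matched to samples by the sample descriptions.

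Of 49585 rows, 49326 (99.5%) had a symbol in the gene name table, and 88.2% carried a versioned identifier found in GENCODE M21, whose GRCm38 coordinates are used throughout. In 21625 rows all 8 libraries had 0. CPM values used the library total, and TMM scaling where a fit was made. Totals ranged from 1610369 to 6237748, so 3 counts, the number that a count of 0 allows, correspond to 0.481 to 1.86 CPM. This floor covers counting error only. Pairs of libraries of the same genotype differed by more than sampling noise, with a chi-square over its degrees of freedom of 2.27 to 24.2. None was therefore counted as a repeated sequencing of another. The ratio does not show whether libraries came from separate cultures or RNA samples.

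Row names were checked with 545 protein-coding genes of ubiquitous families. A checked segment was a run of at least 5 consecutive such genes spanning at least 5 Mb, each at 20 CPM or more in the pooled counts, and 3 were found. This rule was reached by trial. The first one, with runs of 3 at 10 CPM, found 5 segments against a mean of 3.05 after permuting which genes passed (permutation p = 0.19), and was dropped. Other minimums, run lengths and numbers of misses were then compared with their permuted values. Family members known to be restricted to a tissue were left out after their counts had been seen. With those members kept, the minimums of the final rule found 2 segments, so the count of 3 depends on leaving them out. The rule kept gave a permutation p of 0.0003 over 10000 permutations, but that value belongs to a rule picked after such comparisons and is not an independent test. In 18 combinations recomputed here the permuted p ran from 0.000999, the smallest that 1000 permutations give, to 0.707. The rule was set before any test between genotypes. Rows inside a segment that are not ubiquitous genes were taken to be as reliable as their neighbours, which was not checked. No row was reassigned to another gene.

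Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default expression filter by group (a minimum count of 10) and the quasi-likelihood F-test with genotype alone in the model. Calls had a Benjamini-Hochberg adjusted p under 0.05 over the 6580 rows tested. Log2 fold changes are Gata2 KO minus Gata2 f/f, and their SE is the fold change over the root of F. In 28 gene lists, those with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Single values were compared with an exact two-sided permutation test. The design, the gene lists, the naming rule and the alternative settings not named below as added, for the results of that design, were fixed before the data were examined.

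The naming rule took Gata2 first. Then, among rows past the threshold with an average log2 CPM of at least 1 and no overlap between genotypes, it took the 12 largest changes in each direction, leaving out names of the form Gm plus digits, names ending in Rik and clone names. It then took up to 4 members per list with the smallest adjusted p. The same rule was applied again within the checked rows, a choice made after seeing the data. The mitochondrial genes, the ubiquitous genes other than Ube2h, Rrm2b and the list members past the threshold only with the block were also named after their values were seen. Values of 2 list members are not reported here.

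The genotypes share replicate numbers 1 to 4. Deviations from the genotype means of log2 CPM correlated across rows at 0.333, 0.213, 0.243 and 0.804 for numbers 1, 2, 3 and 4, and each library correlated best with its own number. Every correlation was over 0.1, so by a criterion fixed beforehand the numbers were taken to pair the libraries, although no label says what they share. Differently numbered libraries correlated at up to 0.182, so that criterion alone does not tell a shared number from another. The numbers come from the sample titles, and the sample descriptions give same-numbered libraries of both genotypes neighbouring codes. Whether the numbers pair the libraries was decided from the correlations. The model with genotype alone had been fixed as the main one before the data were examined and was kept, although it ignores this pairing. Fits with the replicate number as a block are given where they change a call or move a count by over 1.5 times, and for every gene list whose count of calls they change.

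Alternatives were RLE, upper quartile and no scaling, no filter, a filter of at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, a robust fit, the replicate block, an adjusted p under 0.01, an absolute log2 fold change of at least 1, each library left out, and for lists an estimated correlation, fry and a prior count of 0.5. Added after seeing the data were the checked rows, adjustment over them alone, libraries thinned to the smallest total, leaving out both libraries numbered 4, and for the mitochondrial share, itself compared only after seeing the data, each library left out and swaps of genotype within replicate pairs. Counts were simulated with 200 changed rows among 6580, and with a further list of 20 rows raised, which the false calls leave out. The edgeR step recovered 19.4% of changes of 1.5-fold, 59.7% of 2-fold and 97% of 4-fold, with 8 false calls. Same-numbered libraries shared no deviation in the simulation, unlike in the data, so these rates need not hold for the data.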

Results

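Messenger RNA was sequenced from mouse leukemia cells of bone marrow origin carrying the MA9 label, a common short form for the MLL-AF9 fusion oncogene. The cells either kept intact Gata2 alleles flanked by recombination sites (Gata2 f/f) or had lost Gata2 (Gata2 KO), the gene of a zinc finger transcription factor of blood stem and progenitor cells. Each genotype had 4 libraries, and the comparison asks how the transcriptome differs without Gata2. The total count was 1942499, 2158558, 4129492 and 6237748 in Gata2 KO replicates 1 to 4. It was 2070154, 1610369, 2134344 and 5480086 in Gata2 f/f replicates 1 to 4. The labels do not say whether the replicates came from separate animals or cultures, so the p-values measure only the spread between these libraries.

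Most row names of the table could not be read as the genes that were counted. Of 545 genes of families used by every cell, such as ribosomal proteins, proteasome subunits and splicing factors, 353 (64.8%) lay under 1 CPM, a count scaled to a common library total, when the 8 libraries were pooled. Among ribosomal protein genes this held for 60 of 76. Over all 8 libraries Actb had 10 counts, Rplp0 had 5, Eef1a1 had 11 and the myeloid gene Mpo had 9, while B2m had 0. The row named Adgrd1 held 154001 counts and ranked 6 in the table. Genes are therefore described as genes only on the mitochondrial genome and in 3 checked segments. In the segments every ubiquitous gene kept for the check was counted at 20 CPM or more, as the rule requires. The mitochondrial rows had no such check, and their names were taken as given. Elsewhere a name is only the name of a row. In GRCm38 coordinates the checked segments span chromosome 4 from 3831334 to 49521093, chromosome 6 from 11900292 to 30304539 and chromosome 15 from 31590800 to 38692446. They hold 977 rows and 9.86% of all counts, and the rule behind them was settled after the counts had been seen. Names between 0 and 20 Mb of chromosome 4, where Trp53inp1, Atp6v0d2, Tmem64 and Nsmaf lie, are less certain than the others. There a scan for displaced counts gave 11.8 and 12.8 kb in the 2 sets of genes of the window. Displacements within 5 kb were left out of the scan, so it could not show counts to be in place. Rps20 lies in that window too and was counted at 4028 CPM in the pooled libraries. On chromosome 4 no ubiquitous gene lies between Rps20, which ends at 3835665, and Ube2j1, which starts at 33031416. Names in that stretch, Ttpa among them, rest only on the genes at its ends.

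**Figure D1:**
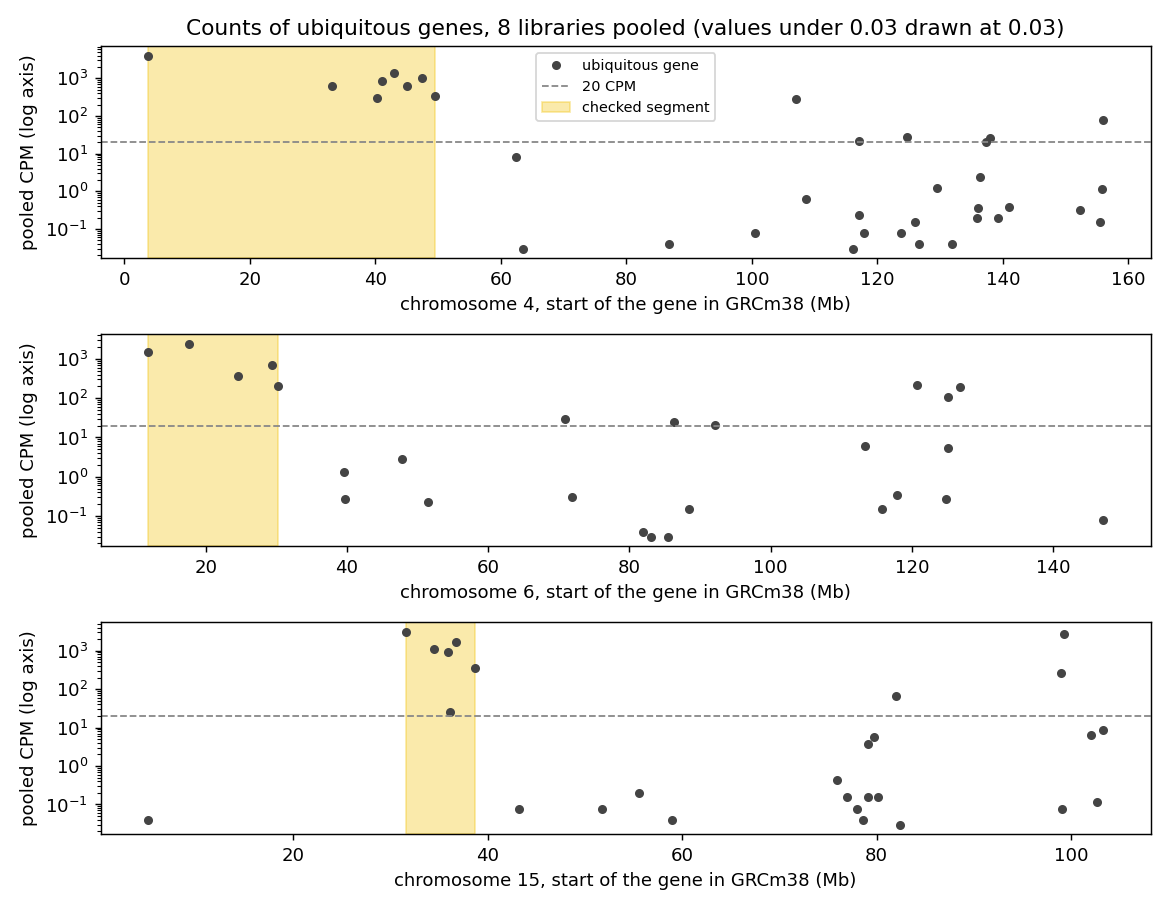
Pooled CPM over 8 libraries (log axis) of each ubiquitous gene on chromosomes 4, 6 and 15, plotted at its GRCm38 start in Mb, with the checked segments shaded and a dashed line at 20 CPM. Every ubiquitous gene inside the 3 shaded segments lies above the line, as the rule for segments requires, and many outside lie under 1 CPM.

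The Gata2 row (ENSMUSG00000015053.14, chromosome 6 from 88193891 to 88207032 in GRCm38) held almost no counts in either genotype. Gata2 f/f replicates 1 to 4 had 0, 0, 1 and 1 counts, and Gata2 KO replicates 1 to 4 had 2, 0, 0 and 0. The mean was 0.163 ± 0.221 CPM in Gata2 f/f and 0.257 ± 0.515 CPM in Gata2 KO (SD, n = 4 each). An exact two-sided permutation test on log2 CPM gave p = 1 over 70 groupings. A library in which the row held 0 counts allows up to 3 counts, between 0.481 and 1.86 CPM over the 8 libraries. Both genotypes lay under that floor, so no fold is given. The row lies outside the checked segments, so the targeted gene does not check the genotype labels.

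In the checked segments the naming rule picked 12 genes higher and 6 lower in Gata2 KO. Irf5, a transcription factor of inflammatory cytokine genes in macrophages, rose from 51.6 ± 10.7 to 259 ± 22.9 CPM (SD, n = 4 each), a log2 fold change of 2.34 ± 0.15 (SE, adjusted p = 6.5e-06, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Trp53inp1, a p53 target that acts in the cell stress response, rose from 66.7 ± 6.53 to 212 ± 33.2 CPM (log2 fold change 1.67 ± 0.14, adjusted p = 3.63e-05, edgeR). Rrm2b, the other member of the p53 target list tested in the checked segments, did not pass. Its log2 fold change was 0.01 ± 0.16 (adjusted p = 0.985, edgeR, and 0.916 with the block). C9orf72, which acts in endosomal traffic and autophagy, rose by 1.89 ± 0.18 on the log2 scale, and Ddx58, the gene of the cytosolic RNA sensor RIG-I, rose by 1.21 ± 0.16. Rragd, a Rag GTPase at the lysosome, rose by 1.99 ± 0.31. Atp6v0d2, a subunit of the vacuolar proton pump found in macrophages and osteoclasts, rose by 3.06 ± 0.66 on the log2 scale. Its mean of 60 ± 60.3 CPM in Gata2 KO rested partly on replicate 3, at 149 CPM. Without that library the log2 fold change of Atp6v0d2 was 2.04 ± 0.42.

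The other genes that the naming rule picked among the higher ones were Stra6l (2.08), Rusc2 (1.92), Glipr2 (1.14), Cav2 (1.13) and Ube2h (0.97), each with its log2 fold change, and Fam214b, at 83 ± 18.2 against 27.4 ± 3.38 CPM (SD, n = 4 each). Impdh1, the gene of an enzyme that limits guanine nucleotide synthesis, was lower in Gata2 KO and went from 211 ± 21.8 to 117 ± 9.24 CPM (SD, n = 4 each), a log2 fold change of -0.85 ± 0.11 (SE, adjusted p = 0.000578, edgeR). Ttpa, the gene of the alpha-tocopherol transfer protein, fell by 1.49 ± 0.26, and Unc13b, which primes vesicles for release, fell by 1.13 ± 0.23 on the log2 scale. Tmem64 fell by 0.69, Pop1 fell by 0.40 and Nsmaf fell by 0.35. Pop1 encodes a subunit of the RNA processing enzymes RNase P and MRP. For these 18 genes the 4 Gata2 KO libraries did not overlap the 4 Gata2 f/f libraries, as the naming rule requires. Their adjusted p, which the rule requires to be under 0.05, lay between 6.5e-06 and 0.0314. Nsmaf lost its call when any 1 library other than Gata2 f/f replicate 4 was left out (adjusted p = 0.0555 to 0.104). Pop1 lost its call without Gata2 KO replicate 3 (adjusted p = 0.07), Gata2 f/f replicate 2 (0.0593) or Gata2 f/f replicate 3 (0.0547).

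**Figure D2:**
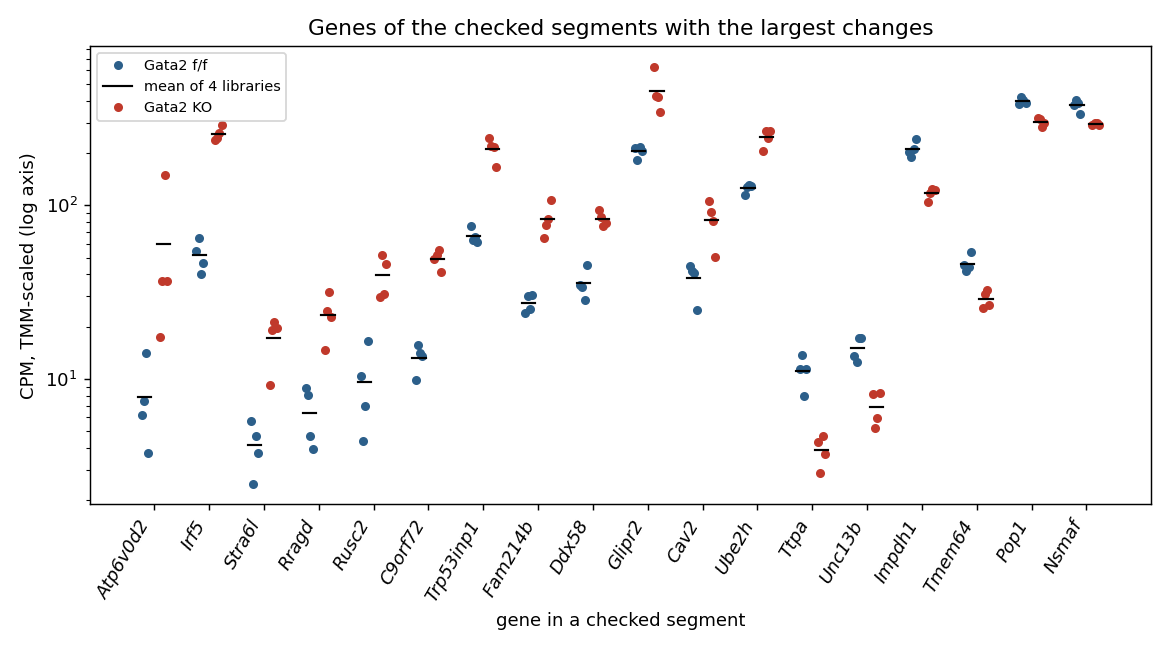
CPM with TMM scaling (log axis) of the 18 named genes of the checked segments, with 1 point per library, blue for Gata2 f/f, red for Gata2 KO, and a bar at the mean of 4 libraries. The genotypes do not overlap for any of the 18, as the naming rule requires, from Atp6v0d2 (log2 fold change 3.06) to Nsmaf (-0.35).

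Of 267 rows tested in the checked segments and on the mitochondrial genome, 31 passed an adjusted p of 0.05, 24 higher and 7 lower in Gata2 KO. With the replicate number as a block, 123 passed, 62 higher and 61 lower. Without Gata2 f/f replicate 4, 51 passed, 30 higher and 21 lower. The lower calls numbered 4 without Gata2 KO replicate 3, Gata2 f/f replicate 2 or Gata2 f/f replicate 3. Of the 19 ubiquitous genes in the segments, Ube2h alone passed in edgeR without the block, and 11 passed with it, 4 higher and 7 lower in Gata2 KO. With the block the higher ones beside Ube2h were Atp6v1f (adjusted p = 0.00152), Ube2j1 (0.0115) and Atp6v1c1 (0.0125). The lower ones were Rps20, Cct5, Mrpl50 (0.0011), Tomm5 (0.002), Polr2k (0.00513), Ndufa5 (0.0142) and Rpl30 (0.0231). Without the block Atp6v1f also passed when Gata2 KO replicate 4 was left out (0.0389), and Cct5 when Gata2 f/f replicate 4 was left out (0.0308) and with library totals (0.0376). Atp6v1f (0.00875), Cct5 (0.00749) and Mrpl50 (0.0413) passed without the block when both libraries numbered 4 were left out. With the block and without both libraries numbered 4, Rps20 (0.0834), Polr2k (0.0818), Atp6v1c1 (0.0649) and Rpl30 (0.0606) no longer passed. Rps20 was at 4113 ± 709 CPM in Gata2 KO and 4616 ± 942 in Gata2 f/f (SD, n = 4 each), and its adjusted p was 0.62 in edgeR and 0.0312 with the block. Cct5, a chaperonin subunit, was at 2929 ± 382 and 3737 ± 535 CPM, and its adjusted p was 0.139 in edgeR and 9.41e-05 with the block.

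Mitochondrial transcripts made up 4.40 ± 0.341% of counts in Gata2 KO and 3.58 ± 0.329% in Gata2 f/f (SD, n = 4 each). The lowest share in Gata2 KO was 4.01%, and the highest in Gata2 f/f was 3.83%. These are shares of a total in which most ubiquitous genes held almost no counts, so they are not shares of the RNA of the cells. The exact two-sided permutation p was 0.0286, the smallest that 70 groupings allow, when the 8 libraries are permuted as independent. With genotypes swapped only within the replicate pairs, all 4 of which were higher in Gata2 KO, p was 0.125, the smallest that 16 swaps allow, so a test that respects the pairs cannot pass 0.05. Of 14 mitochondrial rows tested in edgeR, 13 had a positive log2 fold change and 0 passed an adjusted p of 0.05, while with the block 8 passed, all higher in Gata2 KO. They were the 4 named below, mt-Nd5 (adjusted p = 0.00163 with the block), mt-Rnr2 (0.00195), mt-Rnr1 (0.00423) and mt-Nd4 (0.0065). Without the block mt-Co1 passed when Gata2 KO replicate 4 was left out (0.0423), and mt-Nd5 and mt-Nd4 when Gata2 f/f replicate 4 was left out (0.0311 and 0.0471). DESeq2 called mt-Co1 (0.0294) and mt-Nd6 (0.0475), edgeR with no filter called mt-Co1 (0.0222) and mt-Rnr2 (0.0394), and without both libraries numbered 4 all 8 rows that pass with the block, except mt-Atp6, passed in edgeR. With the block and without both libraries numbered 4, mt-Atp6 did not pass either (0.221). The most abundant row, mt-Co1, a subunit of cytochrome c oxidase, was at 17497 ± 1901 CPM in Gata2 KO and 13223 ± 1499 in Gata2 f/f (adjusted p = 0.0743, edgeR; 0.000569 with the block). Against library totals mt-Co1 held 17221 CPM in Gata2 KO and 13256 in Gata2 f/f, so this row alone made up a large part of the difference in mitochondrial share. The genotypes did not overlap for mt-Co1, mt-Nd6, mt-Cytb and mt-Atp6. The log2 fold changes of mt-Nd6 and mt-Cytb were 0.29 ± 0.10 and 0.31 ± 0.12, with adjusted p = 0.0812 and 0.107 in edgeR and 0.00143 and 0.00241 with the block. For mt-Atp6, at 10.6 ± 1.66 and 6.74 ± 1.99 CPM, the adjusted p was 0.141, and 0.0189 with the block. The mt-Atp6 row lay far below mt-Co1 in both genotypes, and whether it lost reads was not tested.

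Over the whole table, 822 of 6580 rows tested passed the threshold, 590 higher and 232 lower in Gata2 KO. With the replicate number as a block, 2339 passed, 1237 higher and 1102 lower, and all 822 remained among them. The lower calls numbered 133 without Gata2 KO replicate 2, 128 without Gata2 KO replicate 3, 148 without Gata2 f/f replicate 2, 120 without Gata2 f/f replicate 3 and 381 without Gata2 f/f replicate 4. The genotypes did not overlap in 1260 of the rows tested, against a share of 2.86% that chance gives if the 8 libraries are independent. That share ignores the replicate pairs. In the first principal component (42.3% of the variance) the genotypes parted, and in the second (29.1%) the libraries numbered 4 lay apart from the others.

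**Figure D3:**
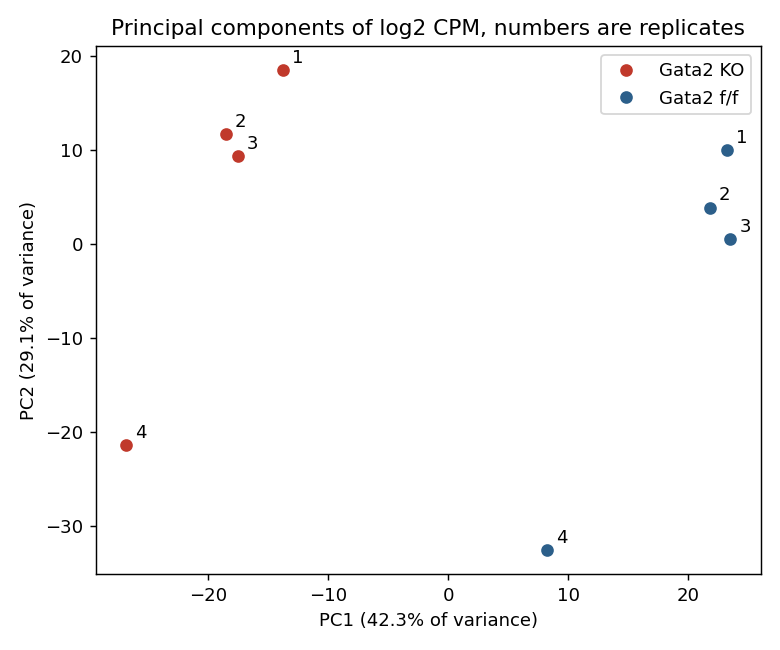
First and second principal components of log2 CPM over 6580 rows, with 1 point per library, blue for Gata2 f/f, red for Gata2 KO, and the replicate number beside each point. The genotypes part along the first component, and both libraries numbered 4 lie at the lower end of the second, at -21.3 and -32.5.

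The naming rule over all rows picked 24 names, of which Atp6v0d2 and Ttpa lie in the checked segments. The other 22 are names of rows, for which no gene function is given. The higher ones were Colec12 (log2 fold change 3.67), Hspa1b (3.17), Gbp9 (2.89), Eno4 (2.81), Kmt2b (2.79), Klf4 (2.76), Rin3 (2.75), Dusp15 (2.65), Zcchc24 (2.63), Mmp12 (2.62) and Mmp8 (2.62). The lower ones were Nebl (-4.40), Arsk (-2.98), Serpine2 (-2.44), Grb14 (-2.42), Ccnd2 (-2.17), Spire2 (-2.13), Podn (-2.04), Rfesd (-1.83), Ppp1r12a (-1.78), Pde9a (-1.50) and Mipol1 (-1.44). Their adjusted p in edgeR lay between 4.21e-06 for Colec12 and 0.0103 for Mipol1. The genotypes did not overlap in any of them, as the rule requires. Some means lay within the 0.481 to 1.86 CPM to which 3 counts correspond. In Gata2 KO these were Nebl (0.669 CPM), Arsk (0.867), Podn, Grb14 and Serpine2. In Gata2 f/f they were Hspa1b (0.794 CPM), Gbp9 and Eno4. The sizes of those changes rest on few counts and are uncertain.

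The 28 gene lists are likewise tests of rows by name. Of their 625 members, 166 were tested and 7 of these lie in the checked segments, where Trp53inp1 and Ddx58 rose and the other 5 did not pass, with or without the block. Over all rows tested, 16 members were higher and 5 lower in Gata2 KO, and 32 were higher and 32 lower with the replicate number as a block. Each count below is followed by the count adjusted over the list alone, and by the count with the block where that differs from the first.

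Among the marker lists of blood cell types, antigen presentation and dendritic cell had 2 rows higher (H2-DMb2, Itgax) and 1 lower (H2-DMb1) of 7, and 3 and 1 adjusted over the list alone. With the block H2-DMa was higher as well. Mast cell and basophil had 1 of 6 higher (Tpsb2), and 2 adjusted over the list alone. With the block all 6 passed and went both ways, 4 higher (Tpsb2, Hdc, Cma1, Cd200r3) and 2 lower (Ms4a2, Slc18a2). Monocyte and macrophage had 1 of 6 higher (Klf4), 2 adjusted over the list alone, and 2 with the block (Klf4, Gpnmb). Secondary granule and mature neutrophil had 1 of 4 higher (Mmp8), megakaryocyte and platelet 1 of 5 (Vwf) and lymphoid 1 of 6 (Il7r), with equal counts adjusted over the list alone. Primary granule and neutrophil progenitor had 1 of 3 higher (Csf3r), and 1 higher and 1 lower adjusted over the list alone. With the block Gfi1 and Gstm1 were lower as well. HSC and progenitor had 1 of 8 lower (Ctnnal1), also adjusted over the list alone. In the lists of eosinophil (3 tested), erythroid (4) and stromal and endothelial rows (4), 0 passed in edgeR, also adjusted over the list alone. With the block Alox15 of the eosinophil list was higher, Ermap of the erythroid list lower, and Pecam1 and Bgn of the stromal and endothelial list higher.

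Among these names Itgax lost its call in edgeR when any 1 library was left out (adjusted p = 0.0541 to 0.127). Il7r, whose libraries overlap between genotypes, kept its call when Gata2 KO replicate 1 or 4 was left out and lost it when any 1 of the other 6 libraries was left out (0.0542 to 0.14). Csf3r lost its call without Gata2 KO replicate 3 or 4 or Gata2 f/f replicate 1, 2 or 3 (0.0738 to 0.114). H2-DMb1 lost its call without Gata2 KO replicate 1 or 2 or Gata2 f/f replicate 3 (0.056 to 0.0755).

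Of the regulatory and signalling lists, NF-kB and inflammatory cytokines had 2 rows of 7 higher (Birc3, Icam1) and 1 lower (Nfkb1). Type I interferon response had 2 of 10 higher (Ddx58, Ifi204), and 2 lower as well with the block (Oas2, Oas3). Hematopoietic cytokine receptors had 2 of 8 higher (Csf3r, Il7r), and 3 with the block (Ptafr as well). GATA2 partner transcription factors had 1 of 5 higher (Nfe2), and 2 with the block (Zfpm1 as well). Of the p53 targets 1 of 6 was higher (Trp53inp1), and Ercc5 was lower with the block. Immediate early and dissociation stress had 1 of 2 higher (Hspa1b). Glycolysis and hypoxia had 1 of 10 higher (Aldoa), and 3 lower as well with the block (Slc2a1, Pfkp, Pgam1). Integrated stress response and amino acid synthesis had 1 of 7 lower (Slc3a2), and 3 with the block (Asns and Aldh18a1 as well). The counts of these lists without the block were equal when adjusted over the list alone.

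G2 and M phase had 1 of 10 lower (Cdc20), 0 adjusted over the list alone, and 5 lower with the block (Cdc20, Ccnb1, Cenpf, Kif11, Cdca8). The mitochondrial respiratory chain had 0 of 10, and 3 higher adjusted over the list alone. With the block 3 were higher and 1 lower. MLL-AF9 leukemia program (9 tested), DNA replication and S phase (10), BCL2 family (7), MYC targets and ribosome biogenesis (3), cholesterol synthesis (8), NRF2 antioxidant (3) and homing and adhesion (5) had 0 in edgeR, also adjusted over the list alone. With the block MLL-AF9 leukemia program still had 0. DNA replication and S phase had 1 higher (Uhrf1) and 3 lower (Mcm6, Mcm7, Mcm10), and BCL2 family had 3 lower (Mcl1, Bcl2l2, Bmf). Bcl2l2 stood far above the others in both libraries numbered 4, and without the block its log2 fold change went from -0.26 to 0.26 when Gata2 f/f replicate 4 was left out, with neither value past the threshold. Nop2 of MYC targets and ribosome biogenesis was lower and Txn1 of NRF2 antioxidant higher. Cholesterol synthesis had 1 higher and 1 lower, and homing and adhesion 1 higher (Pecam1) and 1 lower (Itgal).

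Cdc20 lost its call in edgeR when any 1 library was left out (adjusted p = 0.0668 to 0.151). Aldoa lost its call without Gata2 KO replicate 2, 3 or 4 or Gata2 f/f replicate 1, 2 or 3 (0.0671 to 0.123), and Nfkb1 without Gata2 KO replicate 1, 3 or 4 or Gata2 f/f replicate 1 or 3 (0.0542 to 0.0987). Slc3a2 lost its call without Gata2 f/f replicate 1 or 2 (0.0504 and 0.0515), and Nfe2 and Icam1 without Gata2 f/f replicate 3 (0.0575 and 0.0543). Of the list members named as passing with the block, Cdc20, Hdc, Cma1, Slc18a2, Gfi1, Gpnmb, Pecam1, Bgn, Mcm6, Ccnb1, Kif11, Cdca8, Ercc5, Mcl1, Bmf, Oas3, Nop2, Pfkp, Txn1, Ptafr and Itgal did not pass with the block when both libraries numbered 4 were left out.

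In camera, 0 of the 20 lists with at least 5 tested rows passed, 0 had an unadjusted p under 0.05, and the lowest adjusted p was 0.865. With an estimated correlation the lowest adjusted p was 0.886, and with the block 0.946. In fry, 4 lists passed in one direction: HSC and progenitor and glycolysis and hypoxia lower, mast cell and basophil and p53 targets higher. Its test of change in either direction passed for 13 lists. Of the 4 lists, checked rows held 0 of 8 tested members of HSC and progenitor and 0 of 6 of mast cell and basophil. They held 1 of 10 of glycolysis and hypoxia and 2 of 6 of p53 targets. Aldoa, the only glycolysis row called without the block, was higher. Both set tests therefore concern mostly unchecked row names and decide nothing about the programs named. The median log2 fold change and the direction in camera differed in sign for GATA2 partner transcription factors, NF-kB and inflammatory cytokines, hematopoietic cytokine receptors, the mitochondrial respiratory chain and cholesterol synthesis.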

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

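The tests of ubiquitous genes and of scaling and the counts over splits in the blocked fit were chosen after the results were seen, and the test of depth between replicate numbers and the counts over the 35 splits were set before. Of 262 groups of 4 values examined, 10 had a library far from the other 3, and chance flags about 1 in 20 groups. Gata2 f/f replicate 4 stood apart in 5 of them. Its total was 5480086 counts against 1610369 to 2134344 in the other 3. It had 1279 CPM of mt-Rnr1 against 2306 to 2465, 3.76 CPM of mt-Atp6 against 7.48 to 7.95, and 102 CPM of mt-Tp against 149 to 157. It also had 271 CPM of the row named Bcl2l2 against 95.3 to 111, and Gata2 KO replicate 4 had 242 against 72.1 to 85.2. The row named Cma1 was at 29.5 CPM in Gata2 f/f replicate 1 and at 25.6 to 26.2 in the others. Atp6v0d2 was at 149 CPM in Gata2 KO replicate 3 and at 17.3 to 36.8 in the others. The row named Eno4 was at 12.6 CPM in Gata2 KO replicate 4 and at 10.3 to 10.5 in the others. The row named Serpine2 was at 5.70 CPM in Gata2 f/f replicate 1 and at 8.73 to 9.35 in the others.

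Most ubiquitous genes held almost no counts. Too few reads would leave few of them under 1 CPM in the pooled counts, but 64.8% were. Reads dropped because pseudogenes or paralogs share them would spare the mitochondrial ribosomal protein genes, which have few pseudogenes, but 75.6% of these were under 1 CPM. A candidate explanation is that reads and gene coordinates came from different assemblies: in 14 of 139 windows of 20 Mb the displacement that best aligned counts with exons agreed within 2 kb between both sets of genes into which the window was divided, against at most 3 in 20 permutations. Of these, 10 were displacements of 20 kb or more, against at most 2. Among the shorter ones is chromosome 4 from 0 Mb (11.8 and 12.8 kb), which lies largely in a checked segment, so either names there are displaced too or agreement over a short distance does not show a displacement, and the scan does not decide between them. Rps20, at 4028 pooled CPM in that window, is 1 gene and does not settle it. Displacements within 5 kb were left out, so the scan could not show the counts of any window to be in place. The evidence is limited, since 3 scans with other scores had covered the chromosomes before this test was written, the permutations break up neighbouring genes of like level, and the scan recovered only 12 of 139 windows in a simulation displaced by 150 kb; no biological explanation was tested.

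Same-numbered libraries deviated together, most of all those numbered 4. If depth were the cause, at least 1 of the 4 correlations would fall to 0.1 or less once all libraries were thinned to one depth, but the lowest was 0.184. Differently numbered libraries reached 0.182 before thinning, so a value over 0.1 is not particular to a shared number. A shared batch, day or animal stays open, since no label names one.

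Among the checked rows more were higher than lower in Gata2 KO, 24 against 7. If scaling were the cause, RLE, upper quartile or library totals would even the counts, but the lowest number of higher calls was 24 and the highest number of lower calls 17. With the replicate block the counts were 62 and 61, so the imbalance depends on the model. A difference between the genotypes stays open and untested beyond these fits.

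Of the 35 splits of the 8 libraries into groups of 4, 1 gave 822 calls or more, the real one, and the other 34 gave at most 0. A share of 1 in 35 lies under 5%, but it is the smallest there can be and takes the 8 libraries as independent. The other splits also mix the genotypes, so a genotype difference adds to the spread within their groups. Chance is therefore not excluded. With the numbers taken to pair the libraries, the splits to compare with are the 8 that part all 4 pairs. The real one, 12.5% of them, gave 822 calls and 2339 with the replicate block, and the other 7 gave at most 0 in either fit, but 8 splits are too few for a share under 5%. The remaining splits place at least 1 pair on one side. For gene lists the real split called 0 and the highest of the others 1, and since all 35 splits give 0 or more by construction, their count decides nothing.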

How the results depend on the processing

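The thinned fits, the fits without both libraries numbered 4, all tests of the mitochondrial share and all counts over checked rows were chosen after seeing the data. Of 822 calls, RLE kept 798, upper quartile 796, DESeq2 801, limma-voom 792, the robust fit 816, library totals 739, no filter 652 and at least 1 CPM in 4 libraries 779. Thinning kept 666 of the 781 it tested, and leaving out 1 library kept 526 (without Gata2 f/f replicate 3) to 746 (without Gata2 f/f replicate 4). No call of the 822 changed direction in any fit run. The replicate block gave 2339 calls (1237 higher, 1102 lower), 123 of them in checked rows (62 and 61). It changed no call of a gene list in camera, ended no call of a named gene, and added 18 mitochondrial and ubiquitous genes and 41 of the list members reported, of which 13 and 19 passed in the block without both libraries numbered 4. Without the block 10 of the 18 passed when both libraries numbered 4 were left out, 2 with no filter, 2 in DESeq2 and 1 with library totals. Of the 41, 11 passed without both libraries numbered 4, 3 with thinning, 2 with no filter, 1 with library totals, 1 in limma-voom and 0 to 5 with 1 library left out. Bcl2l2, lower with the block, had log2 fold changes from -0.88 to 0.26 without the block and with 1 library left out. The change of sign came without Gata2 f/f replicate 4, and none of these values passed the threshold. Without both libraries numbered 4 there were 1437 calls (894 and 543), 81 in checked rows (47 and 34), and with the block as well 1727 (1016 and 711) and 101 (54 and 47). An adjusted p under 0.01 left 402 calls (332 and 70), and a log2 fold change of at least 1 left 322 (271 and 51), fewer by construction. Lower calls in checked rows, 7 in edgeR, numbered 12 with upper quartile, 17 with library totals and 14 with DESeq2. For the other shifts the cause was not tested. With 1 library left out, calls ranged from 548 to 1103 (420 to 722 higher, 120 to 381 lower) and in checked rows from 24 to 51 (20 to 30 higher, 4 to 21 lower). The 18 named genes of the checked segments kept their calls in every alternative fit except Pop1 and Nsmaf, which lost theirs with no filter and with some libraries left out. Of the 16 other list members named, RLE left 15 called (not Itgax), library totals 12 (not Csf3r, Itgax, Cdc20 or Aldoa), no filter 11 (H2-DMb1 lost as well), at least 1 CPM in 4 libraries 14 (not Itgax or Cdc20), upper quartile 15 (not Itgax), DESeq2 and the robust fit 15 each (not Cdc20), thinning 12 (not Itgax, Il7r, Cdc20 or Nfkb1), and leaving out 1 library 7 to 13. Itgax and Cdc20 lost theirs without any 1 library, Il7r and Aldoa in 6 of these 8 fits, Csf3r and Nfkb1 in 5, H2-DMb1 in 3, Slc3a2 in 2, and Nfe2 and Icam1 in 1. Atp6v0d2 moved from 3.06 to 2.04 without Gata2 KO replicate 3. For the mitochondrial share p was 0.125 with swaps within pairs, and with 1 library left out 0.0286 or 0.0571, the 2 lowest values that 35 groupings can give. In fry 4 lists passed, against 0 in camera under all settings run. The exact permutation test of Gata2 kept p = 1 under every scaling, and gave 0.429 to 1 with 1 library left out. The Gata2 row failed both expression filters, so DESeq2, limma-voom, the robust fit and the replicate block gave it no value; with no filter its adjusted p in edgeR was 0.95.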

Other observations

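The genes of this paragraph were picked after their values were seen, because the naming rule leaves them out. In the checked segments Tfec, a transcription factor of the MiT family expressed in macrophages, was higher in Gata2 KO by 0.57 ± 0.14 on the log2 scale (SE, adjusted p = 0.0231, edgeR). Creb3, a transcription factor anchored in the endoplasmic reticulum, was higher by 0.89 ± 0.16 (adjusted p = 0.0039). Klf10, a transcription factor induced by TGF-beta, was higher by 0.62 ± 0.13 (adjusted p = 0.00918), and Ggh, the lysosomal enzyme that trims folate polyglutamates, by 0.94 ± 0.24 (adjusted p = 0.0266). Tdrd7 was higher by 0.86 ± 0.11 (adjusted p = 0.000471). In all of them the 4 Gata2 KO libraries lay above the 4 Gata2 f/f libraries. Tfec and Ggh lost their calls when Gata2 KO replicate 1, 2 or 3 or Gata2 f/f replicate 3 was left out (adjusted p = 0.052 to 0.075 and 0.063 to 0.0883), while Creb3, Klf10 and Tdrd7 kept theirs when any 1 library was left out. All 5 were picked from the higher calls, so they say nothing about the balance of directions.

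Outside the checked segments the row named Blk, also picked after its values were seen, held 3659 ± 913 CPM in Gata2 KO and 1198 ± 97.3 CPM in Gata2 f/f (SD, n = 4 each). Which gene its reads came from is not known here.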
